A study of Gallus gallus with 24 samples.

How the data were processed

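Messenger RNA from bone marrow of male commercial broilers was sequenced in 24 samples, 4 in each of 6 groups formed by day (1 or 5 dpi) and state (mock-challenged, challenged and resistant, challenged and susceptible). Per the labels' protocols, RNA with an integrity number above 9.0 was selected with oligo-dT beads and made into libraries with the Illumina TruSeq v2 kit, which does not mark strand, and the libraries were sequenced in 4 lanes of an Illumina instrument, each with 1 library of every group. Which library ran in which lane is not given in the sources used here.

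The deposited values are raw read counts per Ensembl transcript identifier, 1 file per library, followed by 5 tally rows that name no transcript. Per the submitters' processing notes the tools used were TopHat2 2.0.9, Bowtie2 2.1.0, HTSeq 0.5.4p3, edgeR 3.0.8 and R 2.15.3, with no role or order stated. The genome build, the annotation release and the strand setting are not given in the sources used here. The tally rows were kept out of library sizes and tests. Alignments in no feature made up 15.8% to 21.8% of all tallied alignments per library, ambiguous ones 3.60% to 5.75% and non-unique ones 6.34% to 11.1%, and the 2 tallies for low quality and for unaligned reads held 0 in all libraries. Reads in overlapping features or in near-identical copies can be lost to these tallies, and without strand an antisense partner cannot be told apart, so the levels of such transcripts are uncertain.

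A reference table of 25635 chicken genes (assembly GRCg7b) was searched for the identifiers and matched 0 of them. Gene names are therefore not used here, and the 34 gene lists and the gene symbols chosen before the data were examined could not be tested. Transcripts given by identifier follow the rule for files without names: the 2 largest rises and the 2 largest falls by log2 fold change in the first comparison, susceptible versus mock birds at 1 dpi, among transcripts past the threshold, with no overlap between the groups and with a mean of at least 5 CPM. The 3 most abundant transcripts were added after their values were seen.

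Counts were analysed with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr (minimum count 10, minimum total 15), which left 11328 transcripts with 99.9% of the transcript counts, and 1427 of the 6626 left out had a count of 0 in all libraries. Library sizes were scaled with TMM, 1 model with a coefficient for each of the 6 groups was fitted to all 24 libraries (18 residual degrees of freedom, common dispersion 0.06), and quasi-likelihood F tests gave two-sided p-values, adjusted by Benjamini-Hochberg within each of 12 contrasts. A transcript was called at an adjusted p under 0.05. The contrasts were 6 between groups of the same day, 3 between days and 3 differences between days. The standard error of a log2 fold change was taken from the F statistic, and CPM values are TMM-scaled. Library measures were compared by exact two-sided permutation tests, 45 in one family (5 measures, 9 contrasts), whose smallest possible p is 0.0286. Total counts per library of 5.97 M to 23.1 M limit the precision, together with the spread between libraries, and it is lower for transcripts under 1 CPM. In susceptible versus mock birds at 1 dpi, 3.56% of the 844 such transcripts passed the threshold, against 20.6% of the 1603 with 100 to 1000 CPM. These shares also depend on the size of the changes.

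To find a library deposited under 2 names, the counts of each pair of libraries within a group were compared: the chi-square per degree of freedom, near 1 for 2 draws of the same library, was between 19.6 and 115.5, so each library was counted once. Whether replicate numbers pair the libraries was checked from the correlation of deviations from group means. Only for 5 dpi versus 1 dpi in susceptible birds did all 4 same-numbered pairs exceed 0.1 (0.161 to 0.403), and there a replicate block moved the 1988 transcripts to 2535, less than 1.5 times. The pairing there comes from the data alone, since the labels do not say what the number marks.

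The procedure was tested on simulated counts with 200 changed transcripts among 11328. For susceptible versus mock birds at 1 dpi, 16.4%, 62.7% and 89.4% of changes of 1.5-fold, 2-fold and 4-fold were recovered, and 10.4% of the calls were false, and at 5 dpi the recovered shares were 20.9%, 58.2% and 81.8%, with 4.46% false. The estimate of the change in resistant birds along that in susceptible birds at 1 dpi, simulated at 0%, 50% and 100%, came out at -0.545%, 50.2% and 101%. The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with limma 3.58.1, edgeR's likelihood ratio test, no filter, a filter at a mean of 5 CPM, a fit with only the groups compared, library sizes without the 20 most abundant transcripts, the replicate block and leaving out each library in turn. The share of alignments in no feature as a covariate and the removal of the 3 most abundant transcripts were added after seeing the data.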

Results

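Bone marrow, the tissue in which blood cells are formed, was profiled in male commercial broilers of 4 weeks after challenge with avian pathogenic Escherichia coli, a bacterium that causes colibacillosis in poultry. The 24 libraries fell into 6 groups of 4. Mock-challenged birds, challenged birds graded as resistant and challenged birds graded as susceptible were each sampled at 1 day post infection (dpi) and at 5 dpi. Reads assigned to transcripts ranged from 5.97 M to 23.1 M per library (M, mega), with a median of 10.8 M. Group means were 15.8 M in mock, 13.8 M in resistant and 11.8 M in susceptible birds at 1 dpi, and 14.9 M, 9.36 M and 9.17 M at 5 dpi. Between 13722 and 15252 transcript identifiers were detected in each library. The files do not pair these identifiers with gene names, so the transcripts below are described by group and by level, and only 7 are given by identifier. The samples are numbered within groups and each gave its own library, but the labels do not state that each came from a separate bird, so the p-values measure the spread between these samples.

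A few identifiers carried a large part of the counts. ENSGALT00000036373, ENSGALT00000039695 and ENSGALT00000039703, singled out after their values were seen as the 3 most abundant transcripts, together held 30.6% ± 5.08 of the transcript counts in mock birds at 1 dpi (SD, n = 4) and 30.0% ± 5.45 in mock birds at 5 dpi. In resistant birds their share was 18.1% ± 1.43 at 1 dpi and 29.4% ± 4.89 at 5 dpi. In susceptible birds it was 17.5% ± 6.54 at 1 dpi and 6.22% ± 3.11 at 5 dpi. All 4 susceptible libraries at 5 dpi, from 3.45% to 10.3%, lay below all 4 mock libraries of that day, and the exact two-sided permutation test gave p = 0.0286, the smallest value that 4 against 4 allows, which did not pass 0.05 after Benjamini-Hochberg adjustment over 45 tests of library measures (0.0677). The same p values were found for resistant versus mock birds at 1 dpi, for susceptible versus resistant birds at 5 dpi and for 5 dpi versus 1 dpi in resistant and in susceptible birds. Susceptible versus mock birds at 1 dpi gave p = 0.0571 in the exact permutation test (adjusted 0.103), with replicate 2 of the susceptible group at 26.8%. Resistant and mock birds at 5 dpi differed by less than the spread between replicates (exact permutation p = 0.914).

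**Figure D1:**
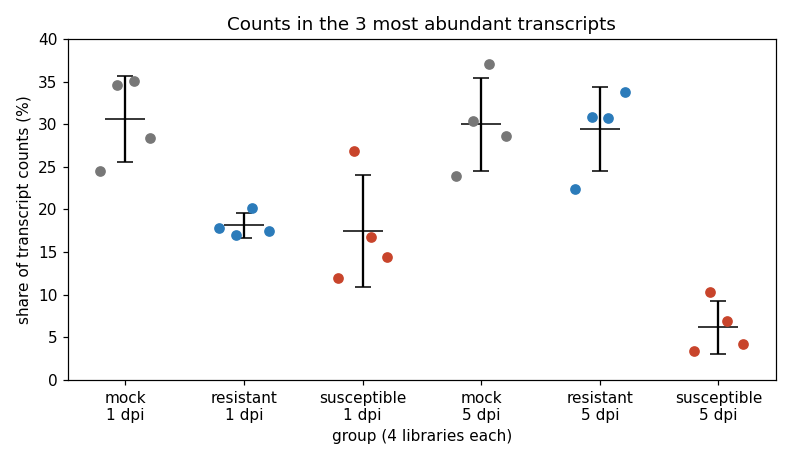
Share of transcript counts, in percent, held by the 3 most abundant transcripts. Points are libraries, horizontal bars are group means and error bars are SD (n = 4), with mock birds in grey, resistant birds in blue and susceptible birds in red. Susceptible libraries at 5 dpi sit between 3.45% and 10.3%, and mock libraries of the same day between 23.96% and 37.1%.

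Per transcript, the level of all 3 was lower in susceptible than in mock birds at 5 dpi. ENSGALT00000036373 fell by 2.51 on the log2 scale (SE 0.38, adjusted p = 3.47e-05), ENSGALT00000039695 fell by 2.96 (SE 0.36, adjusted p = 3.12e-06) and ENSGALT00000039703 fell by 2.81 (SE 0.29, adjusted p = 5.7e-07). Against resistant birds of the same day the log2 changes were -2.57, -2.83 and -2.69, each past the threshold. With the share of alignments in no feature as a covariate they were -1.89, -2.45 and -2.38 against mock and -1.78, -2.21 and -2.15 against resistant birds, again each past the threshold. At 1 dpi, ENSGALT00000039695 (log2 fold change -1.20, adjusted p = 0.0246) and ENSGALT00000039703 (-1.11, adjusted p = 0.0111) passed the threshold in susceptible versus mock birds, and ENSGALT00000036373 (-1.04, adjusted p = 0.0648) did not. The call of ENSGALT00000039695 was lost without replicate 2 or 3 of the mock group (-1.14 and -1.08) and without replicate 1, 3 or 4 of the susceptible group (-1.02, -1.15 and -1.095), and both calls were lost with only these 2 groups in the fit (-1.20 and -1.11) and with the share of alignments in no feature as a covariate (-0.86 and -0.82). ENSGALT00000036373 passed the threshold without replicate 2 of the susceptible group (-1.45) and with DESeq2, limma-voom and edgeR's likelihood ratio test. In resistant versus mock birds at 1 dpi the log2 changes were -1.06, -1.11 and -0.94, with adjusted p of 0.147, 0.1 and 0.0831, and the latter 2 transcripts passed the threshold with DESeq2 and the likelihood ratio test. With a replicate block these 2 passed it as well (-1.04 and -0.875), as did ENSGALT00000036373 in susceptible versus mock birds at 1 dpi (-1.10). The number of transcripts that held 50% of the counts moved the other way, from 124 ± 50.5 in mock to 454.5 ± 61.7 in susceptible birds at 5 dpi. Other measures of the libraries differed between groups as well, not only where the 3 transcripts did. Ambiguous alignments made up 4.13% ± 0.0712 of all tallied alignments in resistant birds at 5 dpi, against 3.82% ± 0.159 in mock birds (exact permutation p = 0.0286, adjusted 0.0677). None of the 3 transcripts passed the threshold in that comparison. In susceptible birds at 5 dpi, ambiguous alignments made up 5.39% ± 0.266 of all tallied alignments and non-unique ones 7.10% ± 0.674, against 3.82% ± 0.159 and 9.15% ± 0.638 in mock birds (exact permutation p = 0.0286 for each, adjusted 0.0677), and alignments in no feature were 20.7% ± 1.05 against 18.2% ± 1.27 (exact permutation p = 0.0571, adjusted 0.103).

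**Figure D2:**
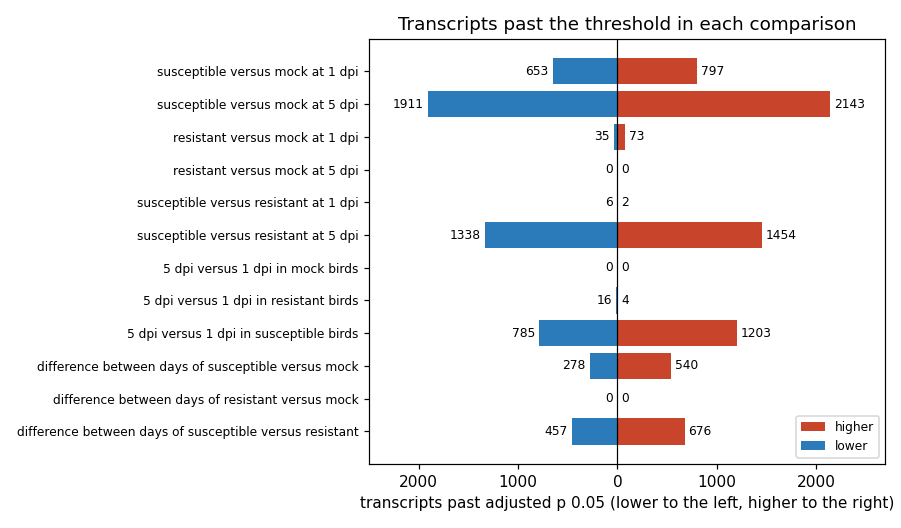
Number of transcripts past an adjusted p of 0.05 in each of the 12 comparisons, with higher transcripts to the right in red and lower ones to the left in blue. The longest bars belong to susceptible versus mock birds at 5 dpi, with 2143 higher and 1911 lower.

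The first comparison asked how the marrow of susceptible birds differed from that of mock birds at 1 dpi. Of 11328 transcripts tested, 797 were higher and 653 lower in susceptible birds, with median log2 fold changes of 0.71 and -0.72. Changes of at least 2-fold were seen for 196 of the higher and 201 of the lower transcripts, and of at least 4-fold for 28 and 40. The largest rise among the transcripts without overlap between groups was that of ENSGALT00000000109, from 0.939 ± 0.609 CPM (counts scaled to library size) in mock to 104.5 ± 28.8 CPM in susceptible birds (SD, n = 4), a log2 fold change of 6.58 (SE 0.67, adjusted p = 1.35e-05). ENSGALT00000019398 rose from 3.04 ± 1.41 to 118 ± 97.7 CPM, a log2 fold change of 5.25 (SE 0.55, adjusted p = 1.35e-05), or 4.48 without replicate 3 of the susceptible group. ENSGALT00000025190 fell from 81.3 ± 8.04 to 8.05 ± 4.40 CPM, a log2 fold change of -3.36 (SE 0.41, adjusted p = 7.13e-05). ENSGALT00000016463 fell from 26.2 ± 34.9 to 3.89 ± 0.888 CPM, a log2 fold change of -2.75 (SE 0.65, adjusted p = 0.00853). Its mock mean rested on replicate 4 at 78.5 CPM, without which the log2 change was -1.15 and no longer past the threshold, and the call was also lost with limma-voom (-1.97), with only these 2 groups in the fit (-2.76) and with the no-feature covariate (-2.39). Of the 1450 transcripts past the threshold, 1130 had no overlap between the 4 libraries of each group, and among all transcripts tested 16.2% had none, where chance gives 2.86%. Among transcripts with a mean above 1000 CPM, 13 were lower and 1 was higher. The count of 1450 fell to 770, 860 and 860 without replicate 1, 3 or 4 of the susceptible group. It was 709 with only these 2 groups in the fit and 754 with the share of alignments in no feature as a covariate.

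**Figure D3:**
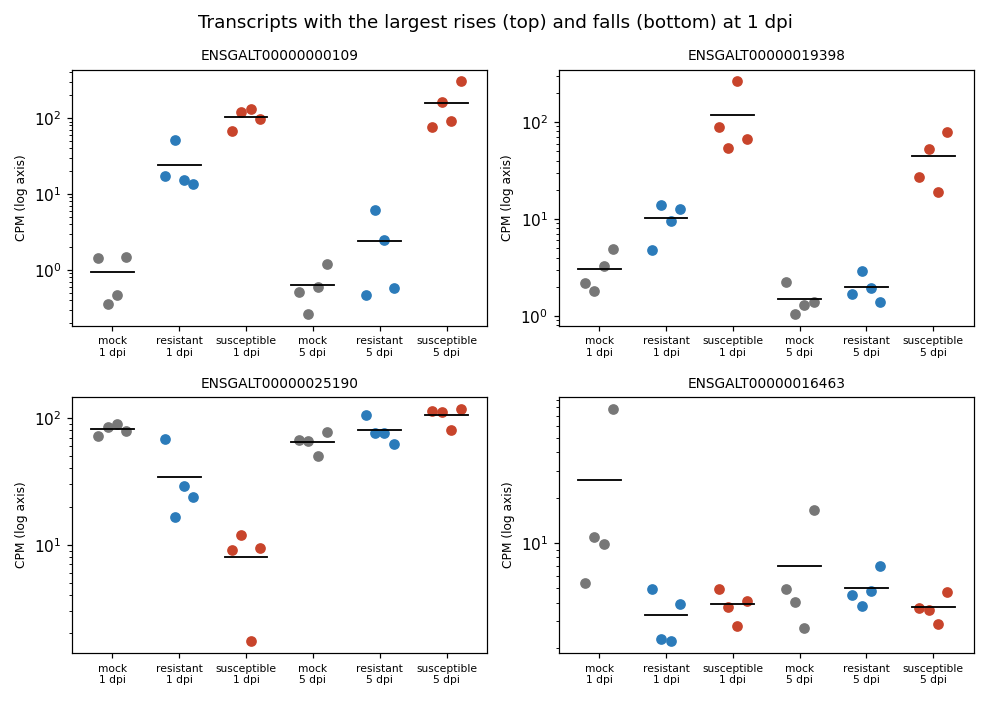
Level in CPM, on a log axis, of 4 transcripts chosen from susceptible versus mock birds at 1 dpi. They have the 2 largest rises and 2 largest falls among transcripts past the threshold, without overlap between groups and with a mean of at least 5 CPM. Points are libraries and bars are means of 4, with mock birds in grey, resistant in blue and susceptible in red. For ENSGALT00000025190, susceptible birds averaged 8.05 CPM at 1 dpi and 106 CPM at 5 dpi.

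At 5 dpi, susceptible birds differed from mock birds in 4054 transcripts, 2143 higher and 1911 lower, which was 35.8% of those tested. The median log2 fold change was 0.89 among the higher and -0.72 among the lower ones. A change of at least 2-fold was found for 866 higher and 622 lower transcripts, and of at least 4-fold for 144 and 89. ENSGALT00000000109 stood at 159.8 ± 104 CPM in susceptible and 0.641 ± 0.396 CPM in mock birds, a log2 fold change of 7.88 (SE 0.72, adjusted p = 1.72e-07). ENSGALT00000019398 stood at 44.4 ± 26.9 against 1.502 ± 0.525 CPM, a log2 fold change of 4.79 (SE 0.56, adjusted p = 1.91e-06). ENSGALT00000025190 was at 106 ± 17.7 CPM in susceptible and 65.1 ± 11.6 CPM in mock birds, a difference that did not pass the threshold (log2 fold change 0.70, adjusted p = 0.137), except with only these 2 groups in the fit (also 0.70). The directions differed by abundance: among transcripts of 1 to 10 CPM, 561 were higher and 266 lower, and among those of 100 to 1000 CPM, 327 were higher and 548 lower. The median log2 fold changes of all transcripts in these classes were 0.18 and -0.15. In resistant versus mock birds of the same day, with 0 transcripts past the threshold, they were 0.14 and -0.06, and in susceptible versus resistant birds 0.03 and -0.09, with 298 higher and 218 lower in the first class and 271 and 391 in the second. Mean depth was 14.9 M in mock, 9.36 M in resistant and 9.17 M in susceptible birds. Under 1 CPM in all 4 mock libraries and above 1 CPM in all 4 susceptible ones were 25 transcripts, and 32 showed the reverse. No overlap between the groups was found for 31.9% of all transcripts tested, where chance gives 2.86%. Leaving out any 1 library gave between 3267 and 4026 transcripts.

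The responses of susceptible birds on the 2 days were compared directly, with a test of the difference between days. Past the threshold on both days were 932 transcripts, of which 527 were higher on both, 379 lower on both and 26 changed in opposite directions; independent lists of these sizes would share 150.8 and 110.2. Of the 1450 transcripts changed at 1 dpi, 1304 (89.9%) had the same sign at 5 dpi. The difference between days itself passed the threshold for 818 transcripts, 540 with a higher and 278 with a lower log2 fold change at 5 dpi. Of the 818, 632 were past the threshold at 5 dpi and not at 1 dpi, 69 at 1 dpi and not at 5 dpi, and 24 on neither day. The estimated changes had the same sign and a larger size at 5 dpi for 369 of them, the same sign and a smaller size for 5, and opposite signs for 444. ENSGALT00000025190 was among these, with a difference between days of 4.06 on the log2 scale (SE 0.55, adjusted p = 0.000988). For ENSGALT00000000109 (1.29, adjusted p = 0.453) and ENSGALT00000019398 (-0.46, adjusted p = 0.767; 0.31 without replicate 3 of the susceptible group at 1 dpi) the difference between days did not pass the threshold. Among the 3 abundant transcripts, ENSGALT00000039695 (-1.76, adjusted p = 0.0306) and ENSGALT00000039703 (-1.69, adjusted p = 0.0116) fell further at 5 dpi, and ENSGALT00000036373 (-1.47, adjusted p = 0.0857) missed the threshold. The call of ENSGALT00000039695 was lost without replicate 1 or 4 of the mock group at 1 dpi (-1.63 and -1.72), replicate 3 of the mock group at 5 dpi (-1.57), replicate 2 of the susceptible group at 1 dpi (-1.31) and replicate 1 or 4 of the susceptible group at 5 dpi (-1.58 for each), and with only these 4 groups in the fit (-1.76). ENSGALT00000036373 passed the threshold without replicate 1 of the susceptible group at 1 dpi (-1.65) or replicate 2 at 5 dpi (-1.86), with DESeq2 (-1.47) and with the likelihood ratio test (-1.47). It also passed with a replicate block (-1.51). Across transcripts, which are not independent replicates, the log2 fold changes of the 2 days correlated at r = 0.502 (Spearman 0.473), with no library in common. The count of 818 was 380 and 532 without replicate 2 or 3 of the susceptible group at 1 dpi, 467 without replicate 4 of the mock group at 1 dpi, 367 and 416 without replicate 3 or 4 of the mock group at 5 dpi and 462 without replicate 4 of the susceptible group at 5 dpi. It was 540 with only these 4 groups in the fit and 1240 with the DESeq2 Wald test.

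**Figure D4:**
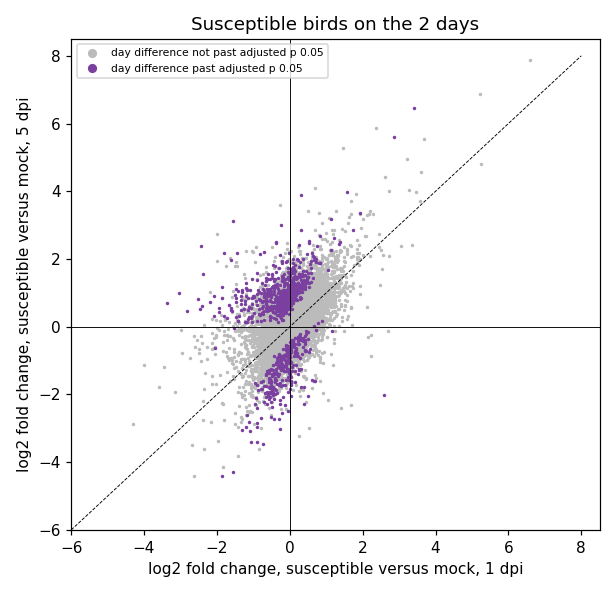
Log2 fold change of susceptible versus mock birds at 1 dpi (horizontal axis) and at 5 dpi (vertical axis) for each of the 11328 transcripts tested, with the line of equality dashed. Purple points are the 818 transcripts whose difference between days passed an adjusted p of 0.05, and 540 of them have the higher value at 5 dpi.

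Resistant birds were compared with mock birds on each day. At 1 dpi, 73 transcripts were higher and 35 lower in resistant birds, with median log2 fold changes of 0.87 and -0.99. ENSGALT00000000109 rose to 24.2 ± 17.8 CPM, a log2 fold change of 4.46 (SE 0.64, adjusted p = 0.00285; 3.80 without replicate 2 of the group), and ENSGALT00000016463 fell to 3.33 ± 1.32 CPM, a log2 fold change of -2.99 (SE 0.65, adjusted p = 0.0278). The fall of ENSGALT00000016463 did not pass the threshold without replicate 4 of the mock group (log2 fold change -1.38), nor without replicate 2, 3 or 4 of the resistant group (-2.86, -2.84 and -3.09), nor with limma-voom (-2.28), with only these 2 groups in the fit (-2.99) or with the no-feature covariate (-2.66). ENSGALT00000019398 was at 10.2 ± 4.04 CPM (log2 fold change 1.72, adjusted p = 0.089) and ENSGALT00000025190 at 34.5 ± 23.1 CPM (log2 fold change -1.24, adjusted p = 0.0904), neither past the threshold. Both passed it without replicate 1 of the resistant group (1.95 and -1.80) and with DESeq2 and the likelihood ratio test, and ENSGALT00000025190 also with limma-voom. The 4 libraries of each group did not overlap for 98 of the 108 transcripts. In susceptible versus mock birds at 5 dpi, a comparison that shares no library with this one, 106 of the 108 had the same sign and 94 passed the threshold, each in the same direction. The count of 108 moved with single libraries, to 176, 46 and 34 without replicate 1, 2 or 4 of the mock group and to 264, 15, 20 and 44 without replicate 1, 2, 3 or 4 of the resistant group. It was 448 with the DESeq2 Wald test, 320 with edgeR's likelihood ratio test, 222 among transcripts of at least 5 CPM, 11 with only these 2 groups in the fit and 12 with the share of alignments in no feature as a covariate. A replicate block gave 259 and brought ENSGALT00000025190 past the threshold (-1.34).

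At 5 dpi, edgeR's quasi-likelihood test found 0 transcripts between resistant and mock birds past the threshold, with 687 at an unadjusted p under 0.05, where 566 would be so by chance. DESeq2, limma-voom and edgeR's likelihood ratio test also gave 0, and so did leaving out any 1 library. ENSGALT00000000109 was at 2.42 ± 2.65 CPM in resistant and 0.641 ± 0.396 CPM in mock birds (log2 fold change 1.65, adjusted p = 0.807; 0.78 without replicate 2 of the resistant group). The 3 abundant transcripts had log2 fold changes of 0.06, -0.13 and -0.12, none past the threshold and each close enough to 0 to change sign with 1 library. ENSGALT00000036373 stood at -0.077 without replicate 1 of the mock group, at -0.003 and -0.07 without replicate 3 or 4 of the resistant group and at -0.11 with the no-feature covariate. ENSGALT00000039695 and ENSGALT00000039703 stood at 0.065 and 0.012 without replicate 3 of the mock group, and the latter at 0.014 without replicate 1 of the resistant group. In counts simulated with the library sizes and dispersions of these data, changes of 2-fold and 4-fold were recovered in 55.2% and 86.4% of cases. Those of 1.5-fold were recovered in 20.9%. The simulated transcripts were drawn independently, without deviations shared between libraries, so recovery in the real data may differ. The difference between days of resistant versus mock birds also gave 0 transcripts with the quasi-likelihood test, with 750 at an unadjusted p under 0.05, and 0 with DESeq2, limma-voom and the likelihood ratio test. Leaving out replicate 4 of the mock group at 1 dpi gave 1. In that contrast the simulated 2-fold and 4-fold changes were recovered in 31.3% and 69.7% of cases.

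Susceptible and resistant birds, both challenged, were then compared with each other. At 1 dpi only 8 transcripts passed the threshold, 2 higher and 6 lower in susceptible birds, with 951 at an unadjusted p under 0.05. ENSGALT00000019398 was higher in susceptible birds (log2 fold change 3.53, SE 0.49, adjusted p = 0.00359; 2.77 without replicate 3 of the susceptible group) and ENSGALT00000025190 was lower (-2.12, SE 0.40, adjusted p = 0.0378). The call of ENSGALT00000025190 was lost without replicate 1, 3 or 4 of the resistant group (-1.56, -2.20 and -2.27), without replicate 1, 2, 3 or 4 of the susceptible group (-2.21, -2.34, -1.78 and -2.23) and with limma-voom (-2.25), and both calls were lost with only these 2 groups in the fit, at nearly the same log2 fold changes (3.53 and -2.11). ENSGALT00000000109 stood 4.34-fold higher in susceptible birds without passing the threshold (log2 fold change 2.12, SE 0.50, adjusted p = 0.13). It passed without replicate 2 of the resistant group (2.76), with limma-voom and with a replicate block (2.24). All 8 were also past the threshold in susceptible versus mock birds at 1 dpi, in the same direction, a comparison that shares the susceptible libraries. The count of 8 was 1, 30, 3 and 2 without replicate 1, 2, 3 or 4 of the resistant group and 1, 1 and 2 without replicate 2, 3 or 4 of the susceptible group. It was 0 with only these 2 groups in the fit, 5 with limma-voom, 46 with edgeR's likelihood ratio test and 56 with the DESeq2 Wald test. A replicate block gave 26.

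At 5 dpi, 2792 transcripts differed between susceptible and resistant birds, 1454 higher and 1338 lower in susceptible birds. Of these, 441 higher and 487 lower transcripts changed at least 2-fold. ENSGALT00000000109 stood 74.8-fold higher (log2 fold change 6.23, SE 0.66, adjusted p = 1.82e-06) and ENSGALT00000019398 was higher too (log2 fold change 4.52, SE 0.58, adjusted p = 1.34e-05). The log2 fold change of ENSGALT00000000109 was 7.10 without replicate 2 of the resistant group and 6.88 with the no-feature covariate. ENSGALT00000025190 did not pass the threshold (log2 fold change 0.40, adjusted p = 0.46). No overlap between the groups was found for 23.3% of all transcripts tested, against 2.86% by chance. The difference between days of susceptible versus resistant birds passed the threshold for 1133 transcripts, 676 with a higher and 457 with a lower log2 fold change at 5 dpi. The 3 abundant transcripts were among them, at -2.59, -2.75 and -2.52 (adjusted p = 0.00426, 0.00199 and 0.00106), as were ENSGALT00000000109 at 4.11 and ENSGALT00000025190 at 2.52 (adjusted p = 0.00336 and 0.00565). ENSGALT00000000109 was at 3.46 without replicate 2 of the resistant group at 1 dpi, at 4.98 without replicate 2 at 5 dpi and at 4.82 with the no-feature covariate, each past the threshold. With that covariate ENSGALT00000036373 (-1.76) no longer passed it, and ENSGALT00000039695 (-2.09) did. With the share of alignments in no feature as a covariate the counts were 1395 at 5 dpi, 609 of them higher, and 363 for the difference between days. The latter was 719 without replicate 3 of the resistant group at 1 dpi, 609 and 747 without replicate 2 or 3 of the susceptible group at 1 dpi, 672 without replicate 4 of the resistant group at 5 dpi and 709 without replicate 4 of the susceptible group at 5 dpi.

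Within each kind of bird, 5 dpi was compared with 1 dpi. In mock birds 0 transcripts passed the threshold with edgeR's quasi-likelihood test, with 988 at an unadjusted p under 0.05. limma-voom also gave 0, the likelihood ratio test 2 and DESeq2 7, and leaving out replicate 1 of the mock group at 1 dpi gave 1. In resistant birds 4 transcripts were higher and 16 lower at 5 dpi. ENSGALT00000000109 was among the lower ones, at an 11.3-fold lower level (log2 fold change -3.49, SE 0.63, adjusted p = 0.0147). The call was lost without replicate 2 at 1 dpi (-2.84) and without replicate 1, 3 or 4 at 5 dpi (-3.09, -3.59 and -3.16), and the value was -4.37 without replicate 2 at 5 dpi, past the threshold. It was also lost with limma-voom (-3.87), with the no-feature covariate (-3.96) and with only these 2 groups in the fit (-3.45). All 20 had passed the threshold in susceptible versus mock birds at 5 dpi with the opposite sign, a comparison without a library in common with this one. The count of 20 was 57, 2, 10 and 8 without replicate 1, 2, 3 or 4 of the resistant group at 1 dpi and 3, 40, 5 and 0 without replicate 1, 2, 3 or 4 at 5 dpi. It was 140 with DESeq2, 108 with the likelihood ratio test, 8 with limma-voom, 12 with no filter on low counts, 2 with the no-feature covariate and 0 with only these 2 groups in the fit.

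In susceptible birds 1988 transcripts changed between the days, 1203 higher and 785 lower at 5 dpi. ENSGALT00000025190 rose 13.4-fold (log2 fold change 3.75, SE 0.42, adjusted p = 2.81e-05) and ENSGALT00000019398 fell 2.67-fold (log2 fold change -1.42, SE 0.45, adjusted p = 0.033). The level of ENSGALT00000019398 at 1 dpi rested in large part on replicate 3, at 262.8 CPM against 53.6 to 89.3 CPM in the others. Without it the log2 fold change was -0.65 and no longer past the threshold, and the call was also lost without replicate 1 or 3 at 5 dpi (-1.23 and -1.16), with the no-feature covariate (-1.23) and with only these 2 groups in the fit (-1.42). The 3 abundant transcripts had log2 fold changes of -1.53, -1.78 and -1.67 (adjusted p = 0.0072, 0.00169 and 0.000516), and the first of these calls was lost with only these 2 groups in the fit (-1.53). The count was 1205 and 1290 without replicate 2 or 3 of the group at 1 dpi and 1065 with only these 2 groups in the fit.

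The changes of resistant and susceptible birds at 1 dpi were set side by side. Of the 108 transcripts changed in resistant birds, 71 were also higher and 32 also lower in susceptible birds, 0 moved in opposite directions past the threshold, and independent lists would share 5.14 and 2.02. Both comparisons use the same 4 mock libraries. With these split into 2 and 2, so that no library was shared, the lists held 440, 392, 646, 753, 937 and 1142 transcripts in susceptible and 71, 124, 19, 27, 0 and 8 in resistant birds, and shared 24, 39, 13, 13, 0 and 6 in the same direction. Across transcripts, which are not independent replicates, the log2 fold changes correlated at r = 0.741, where unchanged groups against the same mock libraries gave 0.503, and at 0.389 with the mock libraries split. The covariance was 0.141 against a simulated 0.0493, and 0.0927 with the mock libraries split. At 5 dpi the correlation was 0.496 against a simulated 0.483, and 0.286 with the mock libraries split, and the covariance was 0.118 against 0.047, and 0.0806 with the split. Along the susceptible change, corrected for the spread between libraries by estimating it from separate libraries of each group, the change in resistant birds amounted to 56% at 1 dpi (42.7% to 71.8% leaving out 1 challenged library) and to 19.1% at 5 dpi (14.8% to 23.1%). These ranges leave out no mock library. The variance of the resistant change itself was 0.0498 at 1 dpi (0.0245 to 0.0763 leaving out any 1 library) and 0.0167 at 5 dpi (-0.0047 to 0.0591). The range at 5 dpi includes 0, so a change in resistant birds on that day was not settled.

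**Figure D5:**
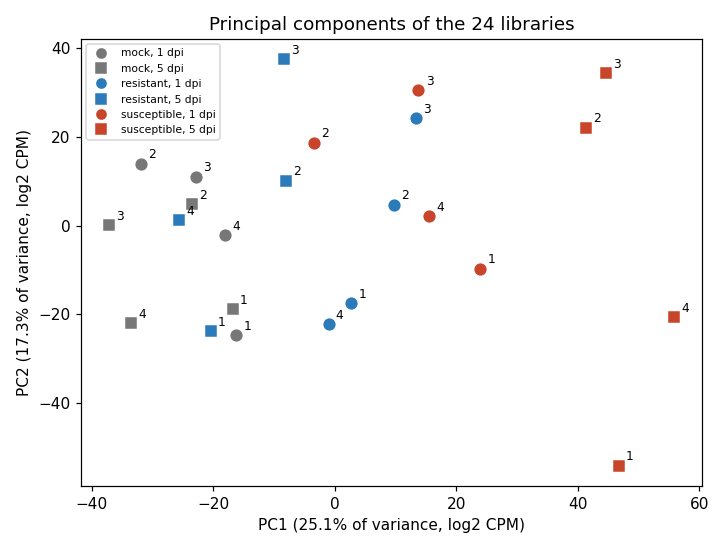
Libraries on the first 2 principal components of the log2 CPM of the 11328 transcripts tested, with 25.1% of the variance on the horizontal and 17.3% on the vertical axis. Circles are 1 dpi and squares 5 dpi, mock birds are grey, resistant blue and susceptible red, and the digit is the replicate number. The 4 susceptible libraries of 5 dpi lie farthest to the right.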

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

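For the share of the abundant transcripts the tests on depth and on the tallies, and for the other patterns those on sequencing lanes, on the second principal component, on 1 atypical library and with the no-feature covariate, were chosen only after the result was seen, and the other tests in this part before. Leaving out each library in turn was itself planned, and only its use as a test of 1 atypical library came later.

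Replicates far from the rest of their group were sought by Dixon's ratio of the gap to the range. Chance gives about 1 in 20 only for independent, normally distributed values. Here CPM were not log-transformed and the library measures are related, so no excess can be read from the count. Such replicates were found in 9 of 78 groups of values. For the library measures these were replicate 1 of susceptible birds at 1 dpi with 20.75% of alignments in no feature (others 18.7% to 19.0%), replicate 1 of mock birds at 1 dpi and replicate 1 of resistant birds at 5 dpi with 190 and 231 transcripts holding 50% of the counts (others 79 to 90 and 81 to 95), and replicate 2 of resistant birds at 5 dpi with 6.397 M counts (others 9.98 M to 10.6 M). ENSGALT00000000109 stood at 50.81 CPM in replicate 2 of resistant birds at 1 dpi (others 13.7 to 17.0). ENSGALT00000019398 stood at 262.8 CPM in replicate 3 of susceptible birds at 1 dpi (others 53.6 to 89.3). ENSGALT00000025190 stood at 79.88 CPM in replicate 3 of susceptible birds at 5 dpi (others 112 to 119). ENSGALT00000016463 stood at 78.45 CPM in replicate 4 of mock birds at 1 dpi (others 5.42 to 10.9) and at 16.45 CPM in replicate 4 of mock birds at 5 dpi (others 2.71 to 4.92).

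A difference between the days, tested as an interaction with edgeR's quasi-likelihood test, was found for 818 transcripts in susceptible versus mock birds and for 1133 in susceptible versus resistant birds. Among the transcripts given by identifier, the difference for susceptible versus mock birds was 4.06 on the log2 scale for ENSGALT00000025190, -1.76 for ENSGALT00000039695 and -1.69 for ENSGALT00000039703. The call of ENSGALT00000039695 was lost without replicate 1 or 4 of the mock group at 1 dpi (-1.63 and -1.72), replicate 3 of the mock group at 5 dpi (-1.57), replicate 2 of the susceptible group at 1 dpi (-1.31) and replicate 1 or 4 of the susceptible group at 5 dpi (-1.58 for each). For susceptible versus resistant birds it was 4.11 for ENSGALT00000000109, 2.52 for ENSGALT00000025190, -2.59 for ENSGALT00000036373, -2.75 for ENSGALT00000039695 and -2.52 for ENSGALT00000039703. That of ENSGALT00000000109 was 3.46 without replicate 2 of the resistant group at 1 dpi and 4.98 without replicate 2 at 5 dpi, and that of ENSGALT00000036373 was -1.76 and not past the threshold with the no-feature covariate.

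The share of the 3 most abundant transcripts was lower in susceptible birds at 5 dpi than in mock birds. Library depth as the cause is argued against by the resistant birds of the same day, whose mean depth was 9.36 M against 9.17 M counts while the share of the 3 transcripts in susceptible birds was lower by 23.2 points (-23.2, susceptible minus resistant). Reads moved into the ambiguous or non-unique tallies are argued against as well, since these tallies together changed by -0.48 points while the 3 transcripts fell by 16.53 points as a share of all tallied alignments. With the share of alignments in no feature as a covariate the log2 fold changes went from -2.51, -2.96 and -2.81 to -1.89, -2.45 and -2.38. Each stayed past the threshold. That share is taken of all tallied alignments, those of the 3 transcripts included, so it rises when these fall and other counts stay. The covariate thus cannot tell a cause of the fall from its result, and whether it accounts for a part stays open. The grade of the birds stays open as a hypothesis, and so does a change in the mix of marrow cells, which was not tested.

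Same-numbered libraries of different groups deviated together, with a mean correlation of 0.172 (highest of the permuted means 0.164, one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The mean for other pairs was -0.057, which largely follows from centring the deviations within groups and is no separate comparison. Removing the trend with the share of alignments in no feature left a mean of 0.09, and removing the trend with log depth left 0.06, so each could account for a part and neither is settled. A shared sequencing lane is a candidate explanation that cannot be told apart from any other shared handling, because the labels do not tie the numbers to lanes. Within groups, the second principal component correlated with the no-feature share at r = -0.452 (permutation p = 0.0422, adjusted 0.0517 over 2 relations; Spearman -0.45, permutation p = 0.0453, adjusted 0.0757; r = -0.294 without the 2 libraries farthest from the median) and with log depth at r = -0.421 (permutation p = 0.0517, adjusted 0.0517; Spearman -0.405, permutation p = 0.0757; r = -0.342 without the 2 farthest), and neither relation passed 0.05 after adjustment. No biological explanation was tested.

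Many transcripts separated susceptible from resistant birds at 5 dpi (2792) and few at 1 dpi (8). One atypical library at 1 dpi is argued against as the cause. Leaving out any 1 library of the 2 groups gave 1 to 30 transcripts at 1 dpi, against 2047 to 2809 at 5 dpi. Without replicate 2 of the susceptible group the count at 1 dpi was 1, a fall that alone decides nothing, since fewer libraries also lower the power. A difference in power between the days is also argued against, since the variance of the effect, estimated from separate libraries of both groups, was 0.0299 at 1 dpi (0.004 to 0.0511 leaving out 1 library) and 0.278 at 5 dpi (0.219 to 0.314), that is 10.8%. The share of alignments in no feature was 20.7% in susceptible and 17.6% in resistant birds at 5 dpi. As a covariate it gave 1395 transcripts at 5 dpi, 7 at 1 dpi and 363 for the difference between days. Such a covariate can also take up effects of the groups it moves with. Being a share of all tallied alignments, it rises where abundant transcripts fall, and so may itself result from the change in expression. Whether it accounts for a part stays open, and so does, as a hypothesis, a biological difference in the timing of the responses of the 2 kinds of bird.

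Other groupings of the same libraries were refitted for each of the 12 contrasts. Susceptible versus mock birds gave 1450 transcripts at 1 dpi (highest other 186, 1 of 35 splits as large) and 4054 at 5 dpi (highest other 120, 1 of 35). Resistant versus mock birds gave 108 at 1 dpi (highest other 5, 1 of 35). Susceptible versus resistant birds gave 2792 at 5 dpi (highest other 378, 1 of 35). The comparison of days in susceptible birds gave 1988 (highest other 344, 1 of 35). These splits argue against chance, but 1 of 35 is the smallest share they allow, so chance is not excluded. The count of 108 was 15 without replicate 2 of the resistant group, 11 with only these 2 groups in the fit and 12 with the no-feature covariate. The real split was also the largest for susceptible versus resistant at 1 dpi (8, highest other 1, 1 of 35) and for 5 dpi versus 1 dpi in resistant birds (20, highest other 0, 1 of 35), but 1 of 35 is the smallest share possible. The count of 8 was 1, 30, 3 and 2 without replicate 1, 2, 3 or 4 of the resistant group, 1, 1 and 2 without replicate 2, 3 or 4 of the susceptible group, and 0 with only these 2 groups in the fit. The count of 20 was 57, 2, 10 and 8 without replicate 1, 2, 3 or 4 at 1 dpi, 3, 40, 5 and 0 without replicate 1, 2, 3 or 4 at 5 dpi, 0 with only these 2 groups in the fit and 2 with the no-feature covariate. Leaving out 1 library can thus bring both down to the highest of the other splits, so for these 2 small counts chance stays open. For the differences between days the splits do not decide, since regrouping within days removes the effects of both days and so tests for no effect at all, not for equal effects. They gave 818 transcripts for susceptible versus mock birds (highest other 487, 1 of 100 drawn splits as large) and 1133 for susceptible versus resistant birds (highest other 1748, 2 of 100). In the splits with 487 and 1748 the 5 dpi libraries of each real group stayed together, with the 2 group labels exchanged in the split with 487. How the 1 dpi libraries were grouped in these splits was not kept. Both splits thus retained the difference between groups at 5 dpi, which may be enough for such counts. Where 0 transcripts passed the threshold there is no count for the splits to test, and every split is as large: resistant versus mock at 5 dpi (highest other 1, 35 of 35), 5 dpi versus 1 dpi in mock birds (highest other 5, 35 of 35) and the difference between days of resistant versus mock birds (highest other 53, 100 of 100).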

How the results depend on the processing

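The covariate for the share of alignments in no feature and the removal of the 3 most abundant transcripts were chosen only after seeing the data. Of the counts and correlations under alternatives other than leaving out a library, 108 stayed within 1.5 times (or within their spread) and 28 moved; of the named log2 fold changes, 690 kept direction and side of the threshold, 24 came past it, 21 no longer passed it and 5 changed sign. DESeq2 size factors, library sizes without the 20 most abundant transcripts and the removal of the 3 most abundant ones moved no count by over 1.5 times. The other values follow, and the cause was not tested for any of them. The DESeq2 Wald test called 448 transcripts in resistant versus mock birds at 1 dpi, 56 in susceptible versus resistant at 1 dpi, 7 between days in mock and 140 in resistant birds, and 1240 for the difference between days of susceptible versus mock. The likelihood ratio test called 320, 46, 2 and 108 in the first 4 of these. limma-voom called 5 in susceptible versus resistant at 1 dpi and 8 between days in resistant birds, where no filter gave 12, and a minimum of 5 CPM gave 222 in resistant versus mock at 1 dpi. With only the groups compared in the fit, and so fewer libraries, the counts were 709 (susceptible versus mock, 1 dpi), 11 (resistant versus mock, 1 dpi), 0 (susceptible versus resistant, 1 dpi), 0 and 1065 (between days, resistant and susceptible) and 540 (difference between days, susceptible versus mock). The no-feature covariate gave 754 and 12 (susceptible and resistant versus mock, 1 dpi), 1395 (susceptible versus resistant, 5 dpi), 2 (between days, resistant) and 363 (difference between days, susceptible versus resistant). With the mock libraries split into 2 and 2 the correlations of effects were 0.389 at 1 dpi and 0.286 at 5 dpi.

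With a replicate block, resistant versus mock at 1 dpi rose to 259 and susceptible versus resistant at 1 dpi to 26, and the other 10 counts moved by less than 1.5 times. Susceptible versus mock birds gave 1923 at 1 dpi, 4570 at 5 dpi and 1197 for the difference between days. Susceptible versus resistant birds gave 3289 at 5 dpi and 1673 for the difference between days. Under the block ENSGALT00000036373 (susceptible versus mock, 1 dpi and difference between days), ENSGALT00000025190, ENSGALT00000039695 and ENSGALT00000039703 (resistant versus mock, 1 dpi) and ENSGALT00000000109 (susceptible versus resistant, 1 dpi) came past the threshold. Over all groups 41 of 60 same-numbered pairs correlated above 0.1 (-0.116 to 0.512), and 16 of 24 libraries correlated best with their own number. By design each lane held 1 library of every group, but the labels do not tie the numbers to lanes. That the number marks such a block is thus only a hint from the data, and the main fit holds no block.

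Leaving out 1 library in turn gave 770 to 1681 transcripts for susceptible versus mock at 1 dpi, 3267 to 4026 at 5 dpi, 15 to 264 for resistant versus mock at 1 dpi and 0 to 0 at 5 dpi, 1 to 30 for susceptible versus resistant at 1 dpi and 2047 to 2809 at 5 dpi. Between days it gave 0 to 1 in mock, 0 to 57 in resistant and 1205 to 2019 in susceptible birds, and for the differences between days 367 to 1095 (susceptible versus mock), 0 to 1 (resistant versus mock) and 609 to 1457 (susceptible versus resistant). The sign changed only for log2 fold changes that were past the threshold in no setting. In susceptible versus resistant birds at 1 dpi, ENSGALT00000036373, at 0.013, was -0.086 with limma-voom, -0.122 with the replicate block, -0.02 with the no-feature covariate, -0.036 and -0.016 without replicate 2 or 4 of the resistant and -0.391 without replicate 2 of the susceptible group (range leaving out 1 library -0.391 to 0.194). ENSGALT00000039695, at -0.088, was 0.1 and 0.024 without replicate 1 or 4 of the susceptible group (range -0.541 to 0.1). In resistant versus mock birds at 5 dpi, ENSGALT00000016463, at -0.493, was 0.361 without replicate 4 of the mock group (range -0.756 to 0.361), and ENSGALT00000036373, at 0.062, was -0.11 with the no-feature covariate, -0.077 without replicate 1 of the mock and -0.003 and -0.07 without replicate 3 or 4 of the resistant group (range -0.077 to 0.248). ENSGALT00000039695, at -0.127, and ENSGALT00000039703, at -0.117, were 0.065 and 0.012 without replicate 3 of the mock group, and the latter 0.014 without replicate 1 of the resistant group (ranges -0.245 to 0.065 and -0.238 to 0.014). Between days in susceptible birds, ENSGALT00000016463, at -0.066, was 0.073 with the no-feature covariate, 0.088 without replicate 1 at 1 dpi and 0.048 without replicate 3 at 5 dpi (range -0.194 to 0.088). The difference between days of susceptible versus mock for ENSGALT00000019398, at -0.461, was 0.313 without replicate 3 of the susceptible group at 1 dpi (range -0.884 to 0.313). The 34 planned gene lists and the named gene symbols were not run, since no identifier matched a name. Depth and replicate number limit what small changes can show: for resistant versus mock birds at 5 dpi, 20.9% of simulated 1.5-fold changes were recovered.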

Other observations

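The tests on positions along the susceptible response were chosen only after the result was seen, and the test on co-varying transcripts before.

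A set of 57 transcripts tracked the 3 most abundant ones within the 4 groups other than mock and susceptible birds at 5 dpi (correlation of within-group deviations over 0.8 across 16 libraries). In susceptible versus mock birds at 5 dpi, libraries that played no part in choosing the set, 42 of the 57 were lower past the threshold, 0 higher and 15 not past it. Their median log2 fold change was -0.96. The medians of all 10000 random sets matched on mean expression lay above it (95% of these between -0.22 and 0.11). By the rule set beforehand, such a low median counted for a wider co-varying set. That rule was dropped after the result was seen, since random sets do not co-vary as the 57 do and so spread less. This comparison therefore decides nothing. These 57 held 1.18% of the transcript counts in mock and 0.633% in susceptible birds at 5 dpi. Whether the fall of the 3 transcripts is part of that of a wider co-varying set, such as the transcripts of 1 kind of cell, is left open as a hypothesis, since the identifiers carry no names here.

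Each library was scored along the susceptible response of the other day, as the mean log2 CPM of the transcripts called higher minus that of those called lower, set to 0 at the mock mean. At 1 dpi, along the 5 dpi response, resistant birds scored 0.598 ± 0.166 and susceptible birds 0.656 ± 0.297 (SD, n = 4), against a mock SD of 0.177. All 4 resistant libraries lay above all 4 mock libraries (difference 0.60, exact two-sided permutation p = 0.0286, adjusted 0.0429 over 6 comparisons), and resistant and susceptible birds differed by less than the spread between replicates (exact permutation p = 0.743). Replicate 2 of the susceptible group, at 0.261, lay below all 4 resistant libraries. So resistant birds stood apart from mock birds on this axis at 1 dpi, in a test chosen after the result. Whether they lie between mock and susceptible birds was not decided. At 5 dpi, along the 1 dpi response, resistant birds scored 0.131 ± 0.151 and susceptible birds 1.44 ± 0.159. The 4 resistant libraries lay below all 4 susceptible libraries (exact permutation p = 0.0286, adjusted 0.0429), and 3 of them above all mock libraries (difference 0.13, exact permutation p = 0.2, adjusted 0.24), so whether resistant birds stood apart from mock birds was not decided.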
